A study of Homo sapiens with 11 samples.

How the data were processed

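Single-cell RNA libraries made with the 10x Genomics 3' kit (chemistry v2) were analysed from 9 established human gastric cancer cell lines. HGC-27 and SNU-16 each gave 2 libraries, and KATOIII, MKN-45, NCI-N87, NUGC-4, SNU-601, SNU-638 and SNU-668 gave 1 each, 11 in all. Per the labels' protocols, the lines grew in standard conditions and were detached with trypsin and strained before capture. Per the submitters' processing notes, Cell Ranger was run against GRCh38; the Cell Ranger version and the gene annotation release are not given in the sources used here.

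For the 5 libraries of HGC-27, SNU-16 and SNU-638 the authors deposited a UMI count for each of 33694 genes in each barcode. For the other 6 libraries the deposited value is a whole-number score: a UMI count that stops at a ceiling of 14 in KATOIII, 7 in MKN-45, 6 in NCI-N87, 8 in NUGC-4, 11 in SNU-601 and 8 in SNU-668. These 6 tables give gene symbols only, list 13283 to 14377 genes, each found in at least 25 barcodes, and hold 2.19 to 2.49% of all entries and 6.92 to 9.74% of their non-zero entries at the ceiling. The unit of the 6 tables was read from the values themselves, since neither labels nor headers state it, and how the ceiling was set is not given in the sources used here. Totals of these 6 libraries are therefore lower bounds of the UMI totals.

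Barcodes of the 5 full tables were kept with at least 1000 detected genes and at most 20% of UMIs from mitochondrial (MT-) genes. In the 6 tables with a ceiling only the gene minimum was applied. This departs from the plan, which set the MT- limit wherever a table lists MT- genes, and these tables list 13. There 69.3 to 79.3% of the MT- entries lie at the ceiling, so the share is a lower bound, at most 2.60% in any cell, and the limit would have removed 0 cells. No doublet caller was run: cells over 2 times the median UMI count of their library, which can be doublets, were kept, and left out only in an alternative. The tables share 10446 genes. A reference set of 8429 of these, each at the ceiling in under 1% of cells of every table with a ceiling, served as denominator: a level is the UMI count of a gene per 1000000 UMIs of the reference set. A level of a gene that reaches the ceiling is a lower bound. For line-specific genes and for oncogenes and neighbours named by fold, a line with over 5% of cells at the ceiling was not the lower side. Medians over the other lines, used for amplicon lists and regions, had no such limit. There the ceilings can raise the log2 of lines with full counts. Counts per 1000000 (CPM) within the full tables refer to all genes. Symbols of the tables without identifiers were matched to those of the full tables, and coordinates came from GENCODE v29 (GRCh38), in which 33132 of the 33694 identifiers (98.3%) were found and 21969 had an unchanged symbol.

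HGC-27 and SNU-16, the only lines with 2 libraries each, were compared on counts summed per library with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. A fold against a line with 0 counts is given as a lower bound against a floor of 3 counts over the line, and with 1 to 3 counts as a ratio of CPM with an exact 95% counting interval. Counting intervals and floors cover counting error only.

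Cells were thinned at random to 1000 reference-set UMIs, cells below that depth were left without a phase, and scanpy 1.11.5 scored the S and G2/M gene lists (43 and 53 genes used) per library. A cell was called G1-like where both scores were at most 0, and otherwise took the phase of the higher score. Counts were then summed per line and phase, with the phase genes removed, and each phase was compared with G1-like cells with the line as a block. The 6 lines with a ceiling were tested by limma on log2(level + 1) of reference-set genes with a mean level of at least 10, and the 3 lines with full counts by edgeR. Genes named for the phases passed both tests and moved the same way in all 9 lines. The difference between the phase effects of HGC-27 and SNU-16 was tested by an interaction term in edgeR on sums per library.

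A gene was called specific to a line with a level of at least 50 and at least 8 times that of every other line listing it, at least 5 of them. For 7 lists of neighbours of genes amplified in gastric cancer, the median log2 level over the median of the other lines was placed among 10000 random lists of matched size and level, and a pair of line and list was called in the top 2.5%. Genes variable between G1-like cells of a line were the 50 with the largest Fano factor (variance over mean) relative to the 100 genes nearest in mean, at a mean of at least 0.5 UMI per cell. A gene was recurrent when among the 50 in at least 3 lines. For these 3 measures, lines hold 1 library or 2, so no test was made. Pearson and Spearman correlations over the 9 lines had exact two-sided permutation p-values, adjusted over 3 relations. Another planned relation, ribosomal protein genes with MYC, was left out since the reference set holds 0 of the 72 genes.

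The comparisons, tests, gene lists, thresholds and the rule for named genes were fixed before the data were examined: for HGC-27 and SNU-16 the 12 largest folds each way with at least 100 CPM in the higher line, for phases the 12 largest each way with a mean level of at least 20, and 2 to 4 members of each list. The lists hold markers of epithelial, mesenchymal, gastric pit and gland, intestinal, stem, fibroblast, immune, endothelial and erythroid cells. Others hold oncogenes, tumour suppressors, the 7 sets of amplicon neighbours, and targets of p53, interferon, NF-kB and hypoxia. The rest hold MHC class I and II, unfolded protein response, heat shock and immediate early, metallothionein, cholesterol, ribosomal, oxidative phosphorylation, spindle, replication and histone, quiescence, S and G2/M genes. Chosen after the values were seen were the reference set and its 1% limit, the 5% limits, the limma filter and the requirement of both phase tests. A first phase scoring drew its control genes from the reference set and phase lists. After its shares were seen, control genes were drawn from all 10446 shared genes, and the first version is kept as an alternative. The limit for variable genes was first 1% of cells at the ceiling; it left too few genes and became 5%, with the ceilings applied to all tables.

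Alternatives covered normalization (RLE), DESeq2 1.42.0, filters on genes and cells, left-out libraries or lines, blocks, thinning, score thresholds, pseudocounts, ceilings applied to all tables, and HGC-27 without barcodes poor in MT- UMIs. In simulated data of like depth, edgeR on 2 against 2 libraries called 88% of genes changed 2-fold and 92% changed 4-fold, with 2.17% of its calls false. The limma test of 6 lines called 78% of genes changed by 0.5 log2 and 99% changed by 1, and edgeR on 3 lines called 23% and 75%. Genes given a 64-fold rise were recovered as line-specific in 80% of cases, and lists given a doubled level in 90%. Nothing in the sources used here says that the libraries came from separate cultures. The p-values of comparisons on sums per library, such as HGC-27 against SNU-16 and the interaction term, therefore measure only the spread between these libraries. Those of the phase tests, on sums per line and phase, measure how the phase differences vary between the lines. Those of the relations come from permuting the lines. Empty droplets are not in the tables used here, so free RNA was not measured. Scripts ran in Python 3.11.15 and R 4.3.3.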

Results

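Transcriptomes of single cells were measured by droplet RNA sequencing (10x Genomics 3' v2) in 9 gastric cancer cell lines, with 2 libraries each for HGC-27 and SNU-16 and 1 for each of the other 7 lines. The labels describe the series as a survey of single cells of these lines and name no treatment. The tables held 1848 and 1769 barcodes for HGC-27, 1078 and 1130 for SNU-16 and 976 for SNU-638, of which 1841, 1758, 1046, 1105 and 968 passed the cell filter. KATOIII gave 3084 cells, MKN-45 2814, NCI-N87 3246, NUGC-4 3797, SNU-601 5186 and SNU-668 5319. Total UMI counts were 38454758 and 50940058 for HGC-27, 39071246 and 46504487 for SNU-16 and 26691546 for SNU-638. The totals of the tables with a ceiling, all lower bounds, were 50389203 for KATOIII, 21981274 for MKN-45, 21868671 for NCI-N87, 32758213 for NUGC-4, 66315679 for SNU-601 and 50227121 for SNU-668. Median UMIs per cell ran from 6390 in NCI-N87 to 38216 in SNU-16 replicate 2.

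HGC-27 expressed mesenchymal genes and SNU-16 epithelial ones. HGC-27 expressed TWIST1, a transcription factor of epithelial-mesenchymal transition, at 455 ± 6.65 CPM (SD, n = 2), at least 12868-fold over SNU-16, where it had 0 counts. VIM, the intermediate filament of mesenchymal cells, stood at 4034 ± 736 CPM in HGC-27 against 13 counts in SNU-16, a ratio of 25251. SNU-16 expressed AGR2, a disulfide isomerase of mucus-secreting cells, at 2596 ± 63.3 CPM, at least 77201-fold over HGC-27 with its 0 counts. The keratins of simple epithelia KRT18 (1829 ± 156 CPM, at least 54401-fold) and KRT19 (990 ± 93.4 CPM, at least 29430-fold) were likewise at 0 counts in HGC-27. By edgeR the adjusted p was 3.50e-17 for TWIST1 (ENSG00000122691, chromosome 7, 19020991 to 19117672, GRCh38), 3.49e-17 for VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593) and 3.42e-17 for AGR2 (ENSG00000106541, chromosome 7, 16791811 to 16833433).

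Other genes had large folds too. In HGC-27, with 0 counts in SNU-16, stood CDKN2A, an inhibitor of cyclin-dependent kinases (ENSG00000147889, 373 ± 30.9 CPM, at least 10533-fold), and the fibrillar collagen gene COL3A1 (ENSG00000168542, 260 ± 8.60 CPM, at least 7359-fold). So did the D-type cyclin CCND2 (238 CPM, at least 6729-fold), the homeobox genes PRRX1 (187 ± 8.68 CPM) and IRX3 (128 ± 6.94 CPM), and IGFBP5, a binding protein of insulin-like growth factors (129 ± 1.76 CPM). LHX9 (318 CPM) and PRAC1 (274 CPM) had 4 and 5 counts in SNU-16. CHODL and ZFHX4 had 1 count each, which gives ratios of 16177 (95% counting interval 2715 to 597580) and 9430 (1552 to 341780). In SNU-16, with 0 counts in HGC-27, stood G0S2, an inhibitor of lipolysis (1233 ± 88.3 CPM, at least 36656-fold), and REG4, a secreted lectin of the gut (435 ± 9.62 CPM, at least 12924-fold). Also there were the gastric mucosal peptide TFF1 (425 ± 18.1 CPM, at least 12648-fold), CEACAM5, the carcinoembryonic antigen (249 ± 8.51 CPM, at least 7398-fold), AGR3 (365 CPM), PRSS3 (333 CPM), MAL2 (275 CPM), GAL (254 CPM) and TSPAN8 (208 CPM).

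All 28 measured epithelial genes were lower in HGC-27 (camera adjusted p = 7.09e-12; adjusted p = 0.265 with an estimated correlation). Their median log2 ratio was -9.41 with genes at 0 counts placed at their bound, and -10.17 as fitted. Of 28 intestinal genes 27 were lower (3.34e-10; adjusted p = 0.265 with an estimated correlation; medians -8.99 and -10.92). These include LGALS4, a galectin of the intestinal lining (1594 CPM in SNU-16, 5 counts in HGC-27), and the cadherin CDH17. CDH1, the epithelial cadherin, had 177 CPM in SNU-16 and 1 count in HGC-27, a ratio of 13581 (2821 to 621030). Of 15 gastric pit and gland genes 13 were lower and 1 higher (0.000186; adjusted p = 0.290 with an estimated correlation; medians -7.87 and -7.80). Of 24 mesenchymal genes 22 were higher in HGC-27 and 2 lower (4.84e-06; adjusted p = 0.290 with an estimated correlation; medians 7.60 and 9.09), and all 11 fibroblast genes were higher (7.06e-05; adjusted p = 0.290 with an estimated correlation; medians 8.72 and 9.28). COL3A1 and the matrix protein gene POSTN are among the latter, and cancer cells with mesenchymal features express such genes too. Adjusted over the list alone, 28 epithelial, 27 intestinal, 14 gastric, 24 mesenchymal and 11 fibroblast genes passed.

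Of 24 oncogenes 19 were lower in HGC-27 and 4 higher (camera adjusted p = 0.00163; adjusted p = 0.301 with an estimated correlation). FGFR2, a fibroblast growth factor receptor, had 1839 ± 23.3 CPM in SNU-16 and 9.48 ± 0.18 in HGC-27 (log2 ratio -7.56, SE 0.13, adjusted p = 3.50e-17). The hyaluronan receptor CD44 had 1654 and 40.7 CPM (log2 -5.30). NF-kB target genes were lower in 12 and higher in 2 of 14 (0.00670; adjusted p = 0.308 with an estimated correlation; median -4.14 at the bounds, -5.19 as fitted): TNFAIP2 differed by -9.69, while CCL2, a monocyte chemokine, was at least 185-fold higher in HGC-27. Heat shock and immediate early genes were lower in 19 and higher in 5 of 25 (0.00816; adjusted p = 0.308 with an estimated correlation), among them the chaperone HSPA1A (-6.35) and EGR1 (-5.03). Of 26 p53 targets 17 were lower and 7 higher (0.0457; adjusted p = 0.358 with an estimated correlation): CDKN1A, which halts the cell cycle, differed by -4.59 and the death receptor FAS by 4.21. Adjusted over the list alone, 23, 14, 24 and 25 genes of these 4 lists passed.

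Ribosomal protein genes were higher in HGC-27 in 50 and lower in 8 of 72 (camera adjusted p = 0.00390; adjusted p = 0.683 with an estimated correlation; median log2 0.54). Nuclear genes of oxidative phosphorylation were higher in 35 and lower in 12 of 55 (0.0154; adjusted p = 0.683 with an estimated correlation; median 0.56). Adjusted over the list alone, 58 and 47 passed. In HGC-27, 902 of 1841 and 887 of 1758 barcodes had under 1% of UMIs from MT- genes, against 1, 4 and 1 barcodes of SNU-16 and SNU-638. Without them the ribosomal list had 45 higher and 11 lower (camera adjusted p = 0.0419, and 0.749 with an estimated correlation, median 0.41). The oxidative phosphorylation list had 28 higher and 19 lower (0.369, median 0.24), so the latter call ended.

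**Figure D1:**
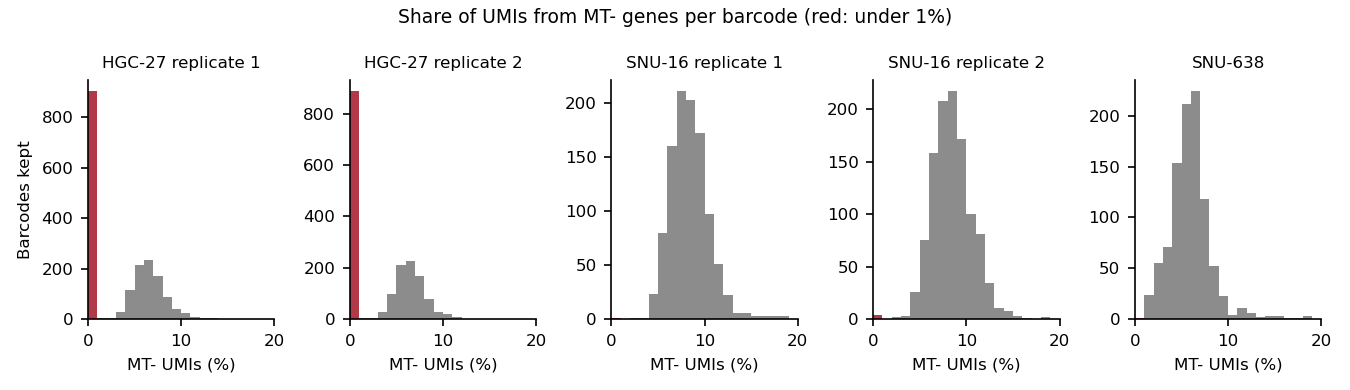
Number of kept barcodes (y axis) by their percentage of UMIs from MT- genes (x axis) in the 5 libraries with full counts, with barcodes under 1% in red. Those number 902 and 887 in HGC-27 and at most 4 in the other libraries.

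Neighbours of amplified oncogenes also separated the lines: the MYC neighbours were higher in HGC-27 in 12 and lower in 3 of 16 (camera adjusted p = 0.0154; adjusted p = 0.330 with an estimated correlation), with NSMCE2, a SUMO ligase, at 442 against 15.1 CPM (log2 4.91, SE 0.11). The adjusted p was 0.0457 for the FGFR2 (3 higher, 10 lower of 14; adjusted p = 0.358 with an estimated correlation), CCNE1 (8 and 1 of 10; 0.381) and CD44 neighbours (3 and 7 of 10; 0.358). Adjusted over the list alone, 15, 13, 9 and 10 of these genes passed. The remaining 16 lists did not pass. Interferon targets were higher in 11 and lower in 15 of 28 (adjusted p = 0.117) and MHC class I genes in 4 and 9 of 15 (0.119). Metallothioneins split 2 and 5 of 7, hypoxia targets 14 and 10, unfolded protein response genes 6 and 13, and cholesterol synthesis genes 8 and 11. Stem cell genes split 8 and 6, tumour suppressors 11 and 8, and ERBB2 and MET neighbours 3 and 11, and 1 and 6. The lists of S, G2/M, spindle, replication and histone, and quiescence genes split 18 and 16, 15 and 32, 16 and 20, 21 and 19, and 8 and 17. Median and mean log2 differed in sign for quiescence (-0.59 and 0.07) and spindle genes (-0.05 and 0.03).

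In all, 7031 of 16632 tested genes were higher in HGC-27 and 6739 higher in SNU-16 by edgeR, with 13898 at an unadjusted p under 0.05. The log2 CPM across genes correlated at r = 0.997 and 0.998 between libraries of a line, and at 0.742 to 0.746 between lines; genes are not independent replicates. Camera called 15 of the 31 lists at the preset correlation and 0 with an estimated one, where 5 had an unadjusted p under 0.05, and fry called 26. With no HGC-27 barcodes under 1% MT- UMIs camera called 12 lists at the preset correlation and 0 with an estimated one. It lost the oxidative phosphorylation list (adjusted p = 0.369, median log2 from 0.56 to 0.24), the CD44 list (0.0522, -3.43 to -3.49), the p53 list (0.0522, -0.82 to -0.95) and the CCNE1 list (0.103, 0.69 to 0.73), and gained the G2/M list (0.0147, -0.30 to -0.48). Without SNU-16 replicate 1 it called 10.

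G2/M-like cells had more RNA of spindle genes than G1-like cells. Genes were named only where they moved the same way in all 9 lines, so that count follows from the choice. KIF14, a kinesin of cytokinesis, rose by 3.59 on the log2 scale (SE 0.20, limma adjusted p = 3.15e-10) in the 6 lines with a ceiling and by 4.74 (SE 0.27, edgeR adjusted p = 1.12e-06) in the 3 with full counts. BUB1B, a kinase of the spindle checkpoint, rose by 2.85 (SE 0.16, 2.73e-10) and 4.07 (SE 0.27, 1.25e-06). SPC25, which couples kinetochores to microtubules, rose by 3.27 and 3.24, and NCAPH, a condensin subunit, by 2.71 and 3.94. The core histone gene HIST2H2BE was lower (log2 -1.72, SE 0.20, 2.92e-06; and -1.74, SE 0.25, 0.000450), and so was MXD4, an antagonist of MYC (-1.69, SE 0.19, 1.59e-06; and -0.75, SE 0.20, 0.0340). KIF14 (ENSG00000118193) lies on chromosome 1 at 200551497 to 200620734, BUB1B (ENSG00000156970) on chromosome 15 at 40161023 to 40221136 and MXD4 (ENSG00000123933) on chromosome 4 at 2247432 to 2262294.

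Other genes higher in G2/M-like cells were the kinesins KIF20A (3.21 and 4.65 on the log2 scale), KIF18B (2.99 and 4.23) and KIF15 (2.90 and 3.67), and SGOL1, the guardian of centromere cohesion (2.68 and 4.12). With them rose CASC5, a kinetochore scaffold (2.92 and 3.80), ERCC6L (2.40 and 4.32), FAM83D (2.89 and 3.70) and ESCO2, an acetyltransferase of cohesin (2.62 and 3.96). Lower were HIST1H2BD (-1.74 and -1.64), the water and glycerol channel AQP3 (-0.98 and -2.03), the iron exporter SLC40A1 (-0.98 and -1.87), SMIM5 (-0.97 and -1.96), RSPH1 (-1.14 and -1.78) and the calcium channel subunit ORAI3 (-1.13 and -1.47). TMEM150A (-1.10 and -1.48), FAM227A (-1.37 and -1.06), METTL7B (-0.82 and -1.51) and YPEL2 (-1.32 and -0.95) completed the 12. Histone genes have near-identical copies, so which copy gave the reads is uncertain. Their levels also count only RNA captured by the 3' kit and need not follow all histone RNA.

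**Figure D2:**
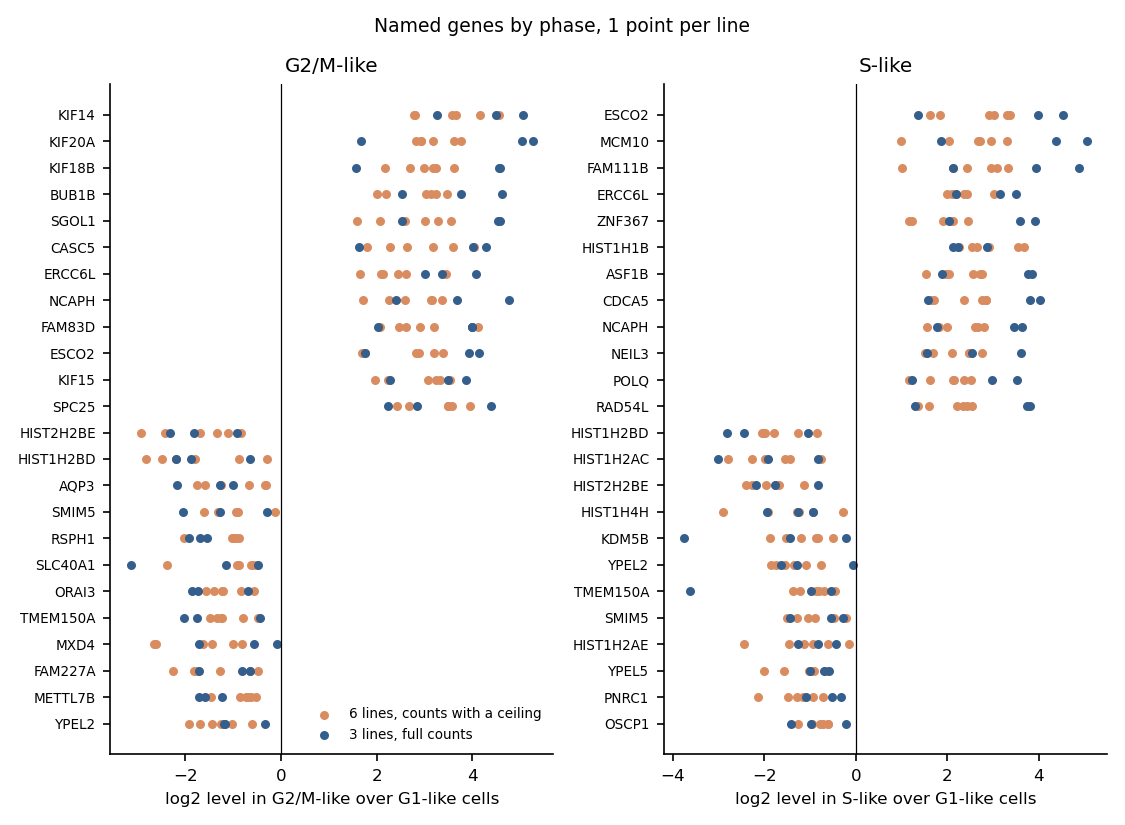
Log2 ratio of the level in G2/M-like (left) or S-like cells (right) over G1-like cells for the 12 largest folds each way, with 1 point per line. Points of the 6 lines with a ceiling and of the 3 lines with full counts lie on the same side of 0 for each gene, which the choice of genes requires.

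All 25 measured spindle genes rose in G2/M-like cells of the 6 lines (median log2 2.63, camera adjusted p = 1.23e-34; adjusted p = 0.0731 with an estimated correlation), and 45 of 45 in the 3 lines (3.16, 6.01e-59; adjusted p = 0.560 with an estimated correlation). Replication and histone genes rose in 31 of 32 (1.19, 3.12e-25; adjusted p = 0.147 with an estimated correlation) and in 36 of 46 with 1 lower (1.33, 3.78e-28; adjusted p = 0.573 with an estimated correlation). In the 3 lines ribosomal protein genes fell in 17 of 72 (3.67e-19), oxidative phosphorylation genes in 4 of 55 (7.99e-07) and interferon targets in 7 of 32 (0.00349), each with adjusted p = 0.573 with an estimated correlation. Adjusted over the list alone, 61, 4 and 12 of these passed. Ribosomal genes could not be tested in the 6 lines, and interferon targets had 2 higher and 6 lower of 10 there (0.560). Unfolded protein response genes had 5 of 8 lower in the 6 lines, short of a call (0.0804). In all, 15 of 17 lists in the 6 lines and 24 of 29 in the 3 lines were not called. Camera with an estimated correlation called 0 lists in each of the 4 phase tests, with 2 at an unadjusted p under 0.05 in each.

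S-like cells had more RNA of the listed replication and histone genes, while several core histone genes outside that list had lower levels. These levels count only RNA captured by the 3' kit, so a fall of all core histone RNA in S-like cells is not shown. MCM10, a replication initiation factor, rose by 2.44 and 4.25 on the log2 scale (6 and 3 lines), ASF1B, a histone chaperone, by 2.26 and 3.28, and the linker histone gene HIST1H1B by 2.93 (SE 0.22) and 2.63 (SE 0.22). ESCO2 rose most by the mean of both (2.68, SE 0.19, limma adjusted p = 1.01e-08; and 4.02, SE 0.37, edgeR adjusted p = 3.33e-05; ENSG00000171320, chromosome 8, 27771949 to 27812640). The histone demethylase gene KDM5B fell (log2 -1.14, SE 0.14, 6.06e-06; and -1.60, SE 0.38, 0.0211; ENSG00000117139, chromosome 1, 202724495 to 202809470).

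Also higher in S-like cells were FAM111B (2.49 and 4.0), ERCC6L (2.35 and 3.76), ZNF367 (1.82 and 3.87), the cohesion factor CDCA5 (2.36 and 3.10), NCAPH (2.24 and 3.20), the DNA glycosylase NEIL3 (2.17 and 3.16), the polymerase POLQ (1.99 and 3.32) and the recombination factor RAD54L (2.07 and 3.21). Lower were the histone genes HIST1H2BD (-1.66 and -2.16), HIST1H2AC (-1.80 and -1.95), HIST2H2BE (-1.87 and -1.68), HIST1H4H (-1.43 and -1.51) and HIST1H2AE (-1.12 and -0.90). YPEL2 (-1.39 and -1.09), YPEL5 (-1.19 and -0.75), PNRC1 (-1.29 and -0.63), OSCP1 (-0.82 and -1.01), TMEM150A (-0.91 and -1.49) and SMIM5 (-0.91 and -1.41) were lower too. Replication and histone genes rose in 32 of 32 in the 6 lines (median 1.53, camera adjusted p = 1.36e-35; adjusted p = 0.112 with an estimated correlation) and in 44 of 46 in the 3 lines (2.21, 1.20e-47; adjusted p = 0.448 with an estimated correlation). Spindle genes rose in 24 of 25 (1.64, 3.97e-23; adjusted p = 0.120 with an estimated correlation) and 36 of 45 (1.73, 1.50e-33; adjusted p = 0.448 with an estimated correlation). In the 3 lines ribosomal protein genes fell in 7 of 72 (3.64e-14; adjusted p = 0.674 with an estimated correlation), epithelial genes in 6 of 28 (0.0183; 0.448) and quiescence genes in 6 of 28 with 1 higher (0.0172; 0.448). Adjusted over the list alone, 36, 12 and 8 of these passed.

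In the 6 lines 1371 of 8078 genes were higher and 2152 lower in G2/M-like cells, and 1388 and 2024 in S-like cells (limma). In the 3 lines the counts among 14967 genes were 805 and 616, and 681 and 441 (edgeR), and DESeq2 called 718 and 590, and 721 and 406. Genes higher in both tests numbered 501 for G2/M, where 96.0 were due by chance, and 469 for S (83.8 by chance). Genes lower in both numbered 206 (61.4 by chance) and 142 (42.3). Without HGC-27 the 3-line counts were 340 and 157 for G2/M and 225 and 39 for S, and without SNU-16 they were 454 and 184, and 472 and 174. The phases were called from RNA, so genes that vary with the scored lists move with the call by its construction.

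The share of cells called S-like or G2/M-like ranged from 47.9% in HGC-27 replicate 1 to 79.9% in KATOIII. HGC-27 gave 47.9% (95% exact Clopper-Pearson interval 45.4 to 50.5, 1510 cells) and 48.7% (46.3 to 51.1, 1721 cells), and SNU-16 58.1% (55.1 to 61.1, 1046 cells) and 58.1% (55.1 to 61.0, 1105 cells). SNU-638 stood at 52.0% (48.7 to 55.2), SNU-601 at 59.8% (58.5 to 61.2), NCI-N87 at 60.2% (58.4 to 61.9) and MKN-45 at 63.7% (61.9 to 65.5). SNU-668 stood at 66.5% (65.3 to 67.8), NUGC-4 at 69.4% (67.9 to 70.9) and KATOIII at 79.9% (78.5 to 81.3). S-like cells were the larger part in SNU-668 (42.8% against 23.7% G2/M-like), and G2/M-like cells in NUGC-4 (45.3% against 24.1%). Among barcodes with at least 1% MT- UMIs, SNU-16 had 40.9 and 38.1% G2/M-like against 17.2 and 19.9% S-like cells. HGC-27 had 29.6 and 30.8% against 11.7 and 13.1% there, so NUGC-4 was not alone in this. The balance in SNU-668 turned with control genes from the reference set (34.2% S-like, 49.1% G2/M-like). HGC-27 barcodes under 1% MT- UMIs had 58.7 and 53.6% S-like or G2/M-like cells, and the others 41.4 and 43.9%. In replicate 1 only 572 of the 902 barcodes under 1% were deep enough to call, against 938 of 939 others. With control genes for the scores from the reference set, SNU-16 was lowest at 65.8% and SNU-638 had 87.7%, so the order of the lines depends on the scoring. Free RNA can enter these calls and was not measured, and 331 of 1841 HGC-27 replicate 1 cells were too shallow to call; the shares are not a measure of proliferation.

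**Figure D3:**
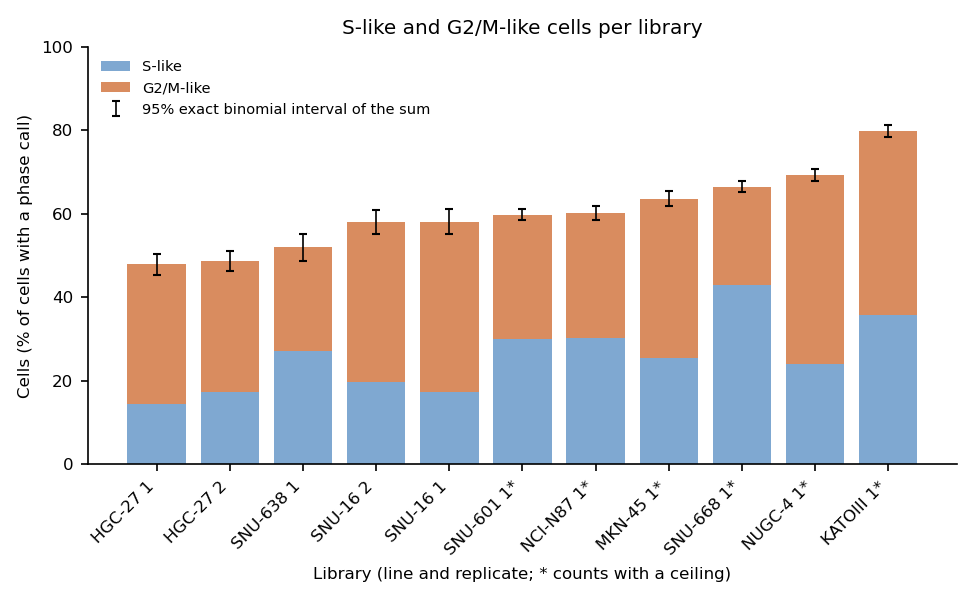
Share of S-like and G2/M-like cells per library in percent of cells with a phase call, with 95% exact binomial intervals of the sum. KATOIII stands highest at 79.9% and HGC-27 replicate 1 lowest at 47.9%.

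Each line had genes of its own, 152 in all. HGC-27 had 38, SNU-668 28, NCI-N87 and NUGC-4 21 each, SNU-638 14, SNU-16 12, KATOIII 7, MKN-45 6 and SNU-601 5. DDR2, a collagen receptor (ENSG00000162733), had a level of 1320 per 1000000 reference-set UMIs in HGC-27, 124 times the next line, and PCOLCE, which aids collagen processing, 41.6 times. FZD8, a Wnt receptor (ENSG00000177283), stood 111 times above the next line in SNU-668, and the growth factor FGF2 37.4 times. CFTR, a chloride channel, stood at least 53.5 times above it in NUGC-4, beside GPD1 (39.8 times) and the chemokine receptor CXCR4 (32.4 times). SNU-638 was marked by MX1, an antiviral interferon target (22.9 times), ARHGAP29 (18.2 times) and the adhesion molecule ICAM1 (17 times). SNU-16 was marked by WDR11 (30.4 times), G0S2 (29.9 times) and FCGBP (26.4 times). NCI-N87 had ZBED2 (42.8 times) and VGLL1 (26.2 times), SNU-601 MMP23B (at least 108 times) and RARRES2 (23 times), KATOIII the keratin KRT6B (at least 19.9 times) and MFNG (15.1 times), and MKN-45 the integrin ITGA10 (14.1 times) and UPK1B (at least 13.4 times). SV2A (47.1 times, HGC-27), LIMCH1 (at least 33.5 times, SNU-668), TNNI2 (21.1 times, NCI-N87), RAMP1 (at least 20.3 times, SNU-601), ULK4 (at least 18.1 times, KATOIII) and CFAP46 (10.6 times, MKN-45) completed the 3 per line. Lines whose table does not list a gene are outside its ratio. With such genes at their highest possible level the total was 260, since the minimum of listing lines falls away, yet named genes lost ground. GPD1, VGLL1, TNNI2, ITGA10 and CFAP46 were then below 8-fold, and SV2A fell to 8.74 times, ICAM1 to 8.92, CXCR4 to 11.9, FGF2 to 16.8, ZBED2 to 17.1, CFTR to 25.7, FZD8 to 27.7, MMP23B to 41.0 and DDR2 to 56.9. RARRES2 fell to 14.8. With each table's own total as denominator the total was 97 and the order of the lines turned: SNU-668 had 35, NCI-N87 15, NUGC-4 14, HGC-27 8, SNU-16 4 and SNU-638 2.

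Oncogenes and their chromosomal neighbours stood out in single lines. ERBB2, a receptor tyrosine kinase, had a level of 2751 in NCI-N87, with 99.2% of cells at the ceiling, at least 6.67 times the next line (NUGC-4, 412). Its neighbours PNMT (17.5 times), TCAP (13.8), PGAP3 (at least 8.81), MED1 (at least 7.26), STARD3 (at least 7.16) and FBXL20 (at least 4.79) stood out there as well. SNU-16 led in WDR11 (30.4 times), a neighbour of FGFR2, and in SLC1A2 (241), APIP (9.48), PDHX (6.55), FAM84B (6.30) and POU5F1B (4.77). HGC-27 led in NSMCE2 (12.2), ZNF572 (11.5), TATDN1 (7.45) and RNF139 (5.57), near MYC, and in PDGFRA (19.1) and NEUROD2 (137). ZNF536 stood at 123 there and at 0 in SNU-16 and SNU-638. SNU-668 led in PAMR1 (785), the receptor gene KIT (14.3) and FJX1 (4.62), NUGC-4 in CFTR, and MKN-45 in ST7, near MET (at least 5.42). Ratios for PAMR1, KIT, SLC1A2 and POU5F1B cover only the 4 lines that list them, those for NEUROD2 3 lines, those for PDGFRA, PNMT and ZNF572 5, and that for CFTR 6. In a table that leaves it out, a gene can still reach a level of 12.5 (SNU-668) to 23.2 (MKN-45). With such lines counted at that level PAMR1 stood 10.0 times and SLC1A2 24.3 times above the next, and KIT (45.2), NEUROD2, PDGFRA, PNMT and ZNF572 were below 8-fold. TFEC, GSDMC, WNT2 and VSTM2B met the 4-fold rule at levels of at most 5.96. Genes chosen after their values were seen were FGFR2, at 10040 in SNU-16 and 2816 in KATOIII with 97.8% of cells at the ceiling, MET, at 2554 in MKN-45 (83.7% at the ceiling) and 2313 in NUGC-4 (49.2%), and MYC, at 1497 in HGC-27 and 949 in SNU-16.

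Among the 63 pairs of line and amplicon list, 12 lay in the top 2.5% of random lists, where 1.58 were due by chance. Of these, 10 are given here. They were the ERBB2 list in NCI-N87 (median log2 over the other lines 3.27) and MKN-45 (0.61), the MET list in MKN-45 (2.36) and NUGC-4 (1.43), and the MYC list in HGC-27 (1.63) and NCI-N87 (0.51). The CD44 list stood out in SNU-668 (1.74) and SNU-16 (0.57), and the FGFR2 list in MKN-45 and SNU-668 (0.75 each). With each table's own total as denominator the MYC list in HGC-27 scored 0.67 and the CD44 list in SNU-16 0.27. Both stayed in the top 2.5%, and the other pairs given here scored higher than before. With ceilings applied to all tables the MYC list in HGC-27 scored 1.39. The MYC list in NCI-N87 lost its place under 5 alternatives, among them a pseudocount of 5 and the mean in place of the median. In the bottom 2.5% lay 8 pairs, 7 of them given here: the MET list in HGC-27 (-2.06) and NCI-N87 (-1.38), ERBB2 in HGC-27 (-1.30), CD44 in KATOIII (-0.74) and NCI-N87 (-0.43), FGFR2 in NUGC-4 (-0.67) and MYC in MKN-45 (-0.57).

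**Figure D4:**
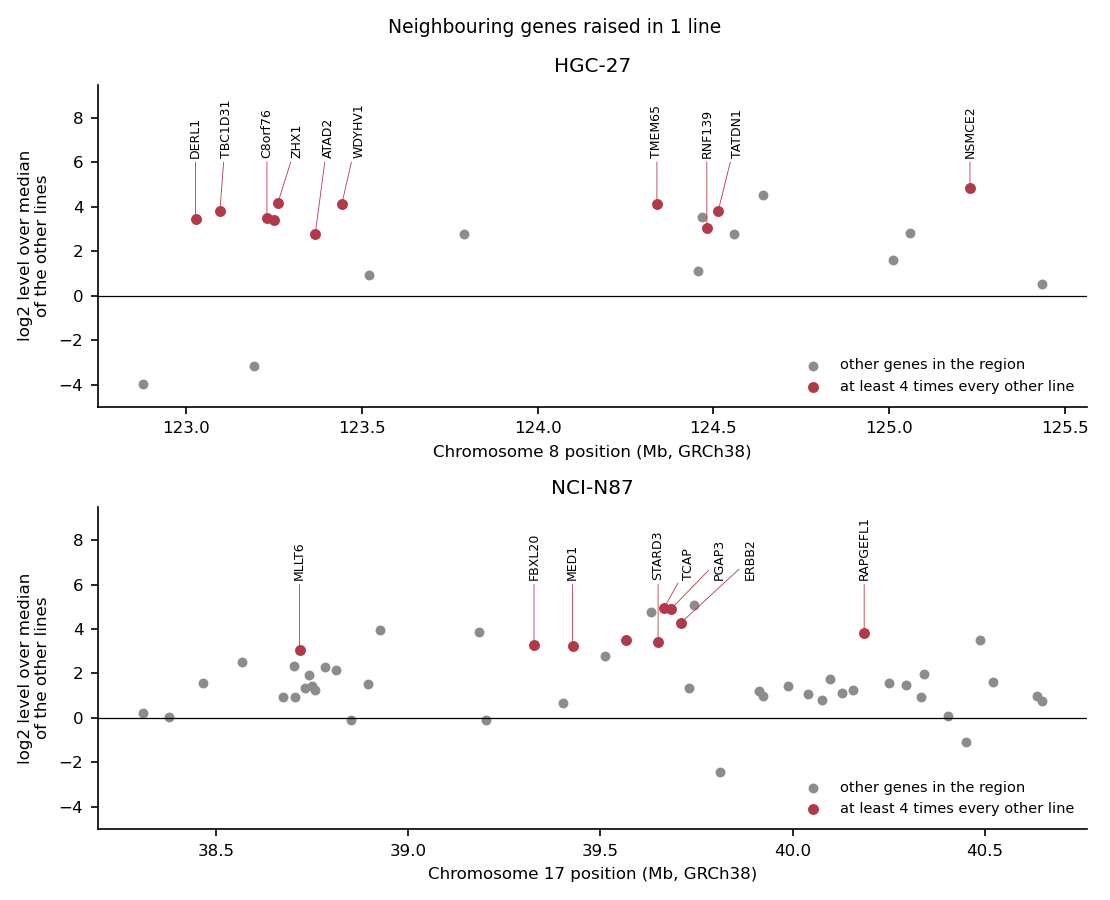
Log2 level over the median of the other lines against gene position for the 2 regions with most raised neighbours, on chromosome 8 in HGC-27 and chromosome 17 in NCI-N87. Red points are genes at least 4 times every other line (11 in HGC-27, 9 in NCI-N87) and grey points other genes within 500 kb.

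Lineage markers differed between lines in kind and level. KRT18 was highest in SNU-638 (19612), EPCAM, an epithelial adhesion molecule, in SNU-16 (2757), and VIM in HGC-27 (24183), with 2703 in SNU-668. Of gastric genes TFF1 was highest in SNU-16 (2325), TFF2 in KATOIII (1872) and the tight junction gene CLDN18 in SNU-601 (1849, 46.5% at the ceiling). The intestinal genes LGALS4 (8722), PHGR1 (3597) and REG4 (2375) were highest in SNU-16, and the stem cell genes RNF43 in NUGC-4 (1462) and SOX9 in MKN-45 (773). Lines with full counts can exceed what the ceilings allow, so a highest place of theirs is no ranking where other lines reach the ceiling.

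None of 3 relations over the 9 lines passed (exact permutation tests, two-sided). The 11 epithelial and 4 mesenchymal genes listed in all tables gave r = 0.225 (p = 0.643, adjusted 0.643) and rho = 0.0167 (p = 0.982), with r = 0.0565 without the 2 farthest lines. Within the 6 lines with a ceiling r was -0.117. Only 4 of the 30 mesenchymal genes are listed in all tables. By these, HGC-27 had a mean log2 level of 5.73 and SNU-16 of 5.71, although 22 of 24 measured mesenchymal genes were higher in HGC-27. The score thus misses that difference, and the relation decides nothing about an opposition of epithelial and mesenchymal expression. The share of S-like or G2/M-like cells with MYC, a driver of growth, gave r = -0.498 (permutation p = 0.171, adjusted 0.256) and rho = -0.750 (p = 0.0255, adjusted 0.0765). It was r = -0.534 without the 2 farthest lines and 0.0722 within the 6 lines. The rho passed without KATOIII (-0.881, permutation p adjusted 0.0217) and without SNU-668 (-0.810, 0.0327). It was -0.200 within the 6 lines and -0.517 (permutation p = 0.162) with each table's own total as denominator. The lines with full counts, HGC-27, SNU-16 and SNU-638, had the lowest shares and the highest MYC levels (1497, 949 and 873). Over the 9 lines this relation can therefore not be told from the kind of table. Interferon targets with MHC class I genes, which interferon induces, gave r = 0.526 (permutation p = 0.145, adjusted 0.256) and rho = 0.400 (p = 0.291, adjusted 0.437). It was r = 0.217 without the 2 farthest lines, -0.106 within the 6 lines, and 0.795 (permutation p adjusted 0.0455) without SNU-668.

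Between G1-like cells of the same line, 17 genes were among the most variable in at least 3 lines. In 4 lines ANXA1, an inhibitor of phospholipase, stood among the 50 most variable genes (median excess log2 Fano factor 0.47), with the transcription factors JUN (0.39) and EGR1 (0.29), the GTPase gene RHOB (0.35) and the stress phosphatase subunit PPP1R15A (0.34). In 3 lines stood the interferon target ISG20 (0.63), HLA-B of MHC class I (0.53), IER3 (0.52), ID2 (0.50), MYC (0.41), FHL2, MALL, MAP1LC3B, MT1X, LMO7, FDFT1 and HNRNPH1. These 17 genes compare with a mean of 2.59 and a highest of 10 in 1000 random draws. The 2 libraries of HGC-27 and of SNU-16 shared 13 of their 50 most variable genes each, where 6.39 and 4.87 were due by chance. Only 458 to 973 genes per library had the depth to be ranked. With a mean of at least 0.2 UMI there were 35 recurrent genes, among them 9 of the 17, with all cells in place of G1-like ones 20 (10 of the 17), with any share at the ceiling 40 (7), and with 100 genes per line 43 (all 17). HGC-27 and SNU-16 were represented by replicate 1 alone. In SNU-16 replicate 2 JUN could not be ranked, FHL2 ranked 55 and MAP1LC3B 258, while ANXA1, not counted for either line, ranked 6 there and 13 in HGC-27 replicate 2. With replicate 2 of both lines there were 18 recurrent genes, 15 of them the same.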

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

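Neither the test of a difference between the phase effects of HGC-27 and SNU-16 nor the tests of its dependence on MT-poor barcodes and on depth were planned; all were chosen after the phase results were seen.

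Phase effects differed between HGC-27 and SNU-16 by an interaction term in edgeR. Of 14683 genes, the G2/M effect was more positive in HGC-27 for 1886 and in SNU-16 for 1085, and the S effect for 1802 and 933. As point values per line, the G2/M effect was larger in HGC-27 for the mitotic genes KIF14 (5.06 against 4.50 in SNU-16) and KIF20A (5.28 against 5.03). Neither is among the named genes that differed by the interaction term. Among the named G2/M genes that differed, the log2 effect in HGC-27 minus that in SNU-16 was -1.67 for SPC25 (SE 0.28, adjusted p = 1.42e-05). It was -1.12 for NCAPH (SE 0.32, 0.00898) and -0.82 for BUB1B (SE 0.23, 0.00743), mitotic genes like SPC25. It was 2.88 for the iron exporter SLC40A1 (SE 0.37, 4.72e-08), 1.24 for the MYC antagonist MXD4 (SE 0.12, 1.35e-11) and 1.06 for FAM227A (SE 0.35, 0.0245). Among those named for S it was 1.49 for FAM111B, 0.82 for the histone gene HIST1H1B, 0.71 for PNRC1 (adjusted p = 3.23e-07) and 0.47 for YPEL5. It was -2.69 for TMEM150A (adjusted p = 1.35e-07), -2.27 for the histone demethylase KDM5B (5.40e-09) and -0.94 for HIST1H2AC.

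The MT-poor barcodes of HGC-27 cannot be the whole source of this difference, since with only cells of at least 1% MT- UMIs 71.4% of the differing genes kept their call and direction for G2/M and 58.5% for S. They bear on its balance, though: without them more genes had the more positive effect in SNU-16 (1050 in HGC-27 and 2095 in SNU-16 for G2/M, 687 and 1812 for S). Unequal depth of cells was tested with sums of thinned counts, where the difference held its size among genes tested both ways (slope 0.938 for G2/M and 0.929 for S), while fewer of 11114 genes passed (491 in HGC-27 and 206 in SNU-16 for G2/M, 555 and 258 for S). A limit of 20 CPM on the genes of that slope was dropped after its first value was seen, which was lower and led to the same reading. A difference between the lines themselves may remain, untested, as each line differs from the other in all that sets lines apart. Free RNA and the accuracy of the phase calls in each line stay open too.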

How the results depend on the processing

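Alternatives chosen after the data were seen were the control genes from the reference set, ceilings applied to all tables, MT-poor barcodes left out, all 9 lines by limma, a pseudocount of 5 for phases, cells over 2 times the median UMIs left out of the shares, the MYC relation under other shares, missing genes at their bound, reference-set genes for relations, and any share at the ceiling. The 52 genes followed in HGC-27 against SNU-16 held direction and call under all 14 alternatives, and both gene counts stayed within 1.5 times. Fits without 1 library say little on calls, since 1 line then has 1 library and the spread comes from the other line alone. With the replicate number as a block the gene counts were 7158 and 6870, with 16 lists. The replicate numbers pair no libraries (correlation of deviations 0.0746). Lists ranged from 10 to 13 without 1 library, and 0 lists passed camera with an estimated correlation, there and in each phase test, where fry called 26, and 13 and 2 for G2/M and 10 and 1 for S. Lists were not run with DESeq2, nor DESeq2 without the block.

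For phases no named gene reversed. Over all alternatives, calls of named genes kept and lost were 407 and 49 for G2/M and 379 and 67 for S in the 3 lines, and 468 and 22, and 464 and 26, in the 6 lines. Without the line as a block, 83 genes were higher and 2 lower for G2/M and 76 and 1 for S in the 6 lines (limma; 303 and 297 at an unadjusted p under 0.05), and 0 in either direction in the 3 lines (edgeR; 214 and 206 unadjusted), with 3 lists for S; differences between lines then enter the error. With each library as its own pair in the block the 3-line counts were 2235 and 2843 for G2/M and 1702 and 2426 for S, since more pairs enter. Sums of thinned counts gave 1358 and 1200 lower genes and 4 S lists in the 6 lines. In the 3 lines, no filter on counts gave 1148 and 977 lower genes, more being tested. Control genes from the reference set gave 406 and 184 lower genes there, the ceiling 1049 lower genes for G2/M with 11 and 10 lists, cells over 2 times the median UMIs left out 282 lower genes for S, and pooled scores 278; the cause was not tested. Leaving out 1 line of 3 gave 340 to 817 higher and 157 to 647 lower genes for G2/M with 8 lists, and 225 to 746 and 39 to 422 for S; fewer lines leave less to test with. Leaving out 1 line of 6 gave 1182 to 1372 higher and 1802 to 2026 lower genes for G2/M, and 1160 to 1361 and 1520 to 1932 for S.

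The range of S-like and G2/M-like shares was 31.6 points, and 25.6 with control genes from the reference set, 36.2 without thinning and 37.3 without MT-poor HGC-27 barcodes (31.2 to 32.0 without 1 library). KATOIII was highest in all of these, and the lowest line was HGC-27, SNU-638 (43.6% at a score threshold of 0.05, 50.9% with pooled scores) or SNU-16 (65.8% with control genes from the reference set). Line-specific genes numbered 430 at 4-fold, 52 at 16-fold, 97 with each table's own total and 260 with missing genes at their bound. The amplicon pairs ranged from 11 to 15. Recurrent variable genes numbered 35 at a mean of 0.2 UMI, 43 with 100 genes per line and 40 with any share at the ceiling. The epithelial and mesenchymal relation turned to -0.251 without HGC-27 (up to 0.354 without other lines), -0.117 in the 6 lines and -0.444 with reference-set genes; the MYC relation to 0.0722 in the 6 lines (-0.728 to -0.306 without 1 line); the interferon relation to -0.106 in the 6 lines, and it passed at 0.795 without SNU-668 (lowest 0.0965 without HGC-27). The cause of these was not tested. Ceilings limit the rank of abundant genes in 6 lines, and depth limits phase calls in 331 of 1841 HGC-27 replicate 1 cells.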

Other observations

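Of the tests here, the nearest-line test of MT-poor barcodes, the matching of noncoding genes on length and the exchanges of phase labels were chosen after the result was seen.

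Some interferon targets and metallothioneins were highest in SNU-638; these were picked after their levels were seen, and the lists were not tested across lines. Levels per 1000000 reference-set UMIs were 16254 for IFI27, 6512 for the ubiquitin-like ISG15 (next SNU-601, 1366), 6510 for IFI6 (next SNU-601, 1555), 3237 for the virion tether BST2 (next NCI-N87, 1696) and 1191 for IRF7, a transcription factor of the antiviral response. Other interferon targets were highest elsewhere, such as PARP14 in NCI-N87 (284) and OAS1 in SNU-16 (277). IRF7 reached at most 152 in the other lines that list it. MT2A, a metallothionein that binds zinc and copper, stood at 41971 in SNU-638, 4775 in HGC-27, and MT1E at 14878 (next KATOIII, 2536), while MT1G was highest in KATOIII (872). CD74, the invariant chain of MHC class II, was highest in SNU-638 too (394), while among the other class II genes HLA-DMA in SNU-601 was highest (80.7). SNU-638 has full counts and 6 of the lines do not, so the ceilings lower their levels of the abundant genes, with up to 86.2% of cells at the ceiling for IFI27. One library per line gives these levels no spread.

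Markers of other cell types were looked up as levels. Of 13 immune genes PTPRC, carried by all leukocytes, reached at most 0.492 in the lines with full counts. The tables with a ceiling leave it out, and a gene left out can still reach 12.5 (SNU-668) to 23.2 (MKN-45) there. LYZ, which gastric epithelium also expresses, reached 2967 in NUGC-4 with 99.7% of cells at the ceiling, CD68 655 and CD14 192 in SNU-668. Of 9 endothelial genes ENG reached 67.7 in HGC-27 and CDH5 42.6 in SNU-668, and of 7 erythroid genes HBA1 96.6 in HGC-27. Of 13 fibroblast genes COL3A1 reached 2625 in SNU-668 (85.3% at the ceiling) and 1563 in HGC-27, COL1A1 1357 and DCN 654 in HGC-27. Nearest of the 9 line profiles was the own line for all but 9 KATOIII and 15 SNU-601 cells, though each profile included the cells compared with it.

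In HGC-27, 49.0 and 50.5% of barcodes held under 1% MT- UMIs, at medians of 0.118 and 0.0843% against 6.43 and 6.4% in the rest, with 8903 and 12206 against 29946 and 41398 UMIs. Relative to the rest they were rich in oxidative phosphorylation genes (55 of 55 higher, median log2 1.30, camera adjusted p = 1.52e-20; adjusted p = 0.943 with an estimated correlation) and ribosomal protein genes (69 of 72, 0.84, 2.14e-10; 0.943). Cell-cycle lists were higher too by camera: spindle (30 higher and 7 lower of 45, fitted median 0.72, 6.34e-05) and G2/M genes (36 and 10 of 54, 0.56, 8.43e-05). So were S genes (24 and 4 of 43, 0.50, 0.000105) and replication and histone genes (20 and 9 of 46, 0.27, 0.0448). Stem cell genes were lower (7 of 12, -1.52, 0.0388). Each of these lists stood at 0.943 with an estimated correlation. Fry called 0 of 28 lists (lowest adjusted p = 0.132). Among single genes the fitted log2 ratio was 1.17 for GAPDH, at 4406 and 4862 against 2933 and 3193 CPM. It was 0.77 for VIM, at 3777 and 5205 against 3432 and 4346 CPM. The fitted values lay above these ratios of CPM, so small positive medians of the lists need not be rises in CPM. Nuclear RNAs were lower, MALAT1 by a log2 ratio of -5.44, NEAT1 of -4.38 and KCNQ1OT1 of -5.65, as were the long transcripts of AHNAK (-3.12) and FLNA (-3.62). By rising transcript length, in 4 groups, the median ratio of 8688 coding genes was 0.91, 0.34, -0.18 and -0.79 (Spearman rho -0.572 across genes, which are not independent). By edgeR 4500 of 13971 genes were higher and 5618 lower.

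Another cell line stays open. In either library 100% of the MT-poor barcodes lay nearest to HGC-27, but the HGC-27 profile included these barcodes. Only lines of this series were compared, so the nearest-line test cannot decide. The tables argue against droplets of free RNA of 1 profile, as G2/M genes varied between MT-poor barcodes. The median Fano factor of these genes was at least 1.54 (1.05 for other genes of like mean). Low depth cannot be told apart from the MT state within HGC-27, since 94.3 and 98.9% of barcodes in the middle range of their UMI totals were MT-poor, yet of barcodes of that depth 0 of 252 were so in SNU-638, and 0 of 40 and 4 of 17 in SNU-16. The 2 libraries straddle the 95% set beforehand, and the lower of them was made to decide only after both were seen. Cell fragments without nuclei and mitochondria stay open: the median of 337 long noncoding genes relative to coding genes of like level was 0.34 (95% interval 0.23 to 0.44), and -0.37 (-0.47 to -0.26) with length matched too. Both lie above -0.5, the bound set beforehand against fragments, so by that bound fragments would be argued against. They are left open on grounds seen only afterwards: the genes went both ways, 24.9% lying below -1 with length matched, many noncoding RNAs need not be nuclear, and the 3 nuclear RNAs above, left out of this test, fell far more. A biological state was not tested.

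Some genes at least 4 times above every other line lay near each other: 105 pairs within 1 Mb in the same line, where 1000 shuffles of positions gave at most 41 (mean 20.7). Most lay in HGC-27 (39) and NCI-N87 (38). The largest groups were 11 genes in HGC-27 from DERL1 to NSMCE2 (chromosome 8, 123013164 to 125367120) and 9 in NCI-N87 from MLLT6 to RAPGEFL1, with ERBB2 (chromosome 17, 38705542 to 40195656). Other genes within 500 kb of these had medians of 1.59 and 1.35.

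Chance placement is argued against by the 105 pairs, and reads shared by overlapping or same-family genes by the 97 pairs left without these, against at most 38 in the shuffles. A gain of the whole region may lie behind some groups. In the largest groups of HGC-27 and NCI-N87 the other genes had medians of 1.59 and 1.35, above the bound of 0.5 set for a gain. That bound was set for all pairs together, where the median log2 was 0.49 (95% interval 0.41 to 0.60). This lay just below it and above the bound set against a gain. Over all pairs a gain could therefore not be told from shared regulation. No DNA data were analysed here.

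The phase labels were also exchanged within lines. In the 6 lines only the real labels, 1 of 32 exchanges, gave as many genes, with 3523 against at most 1112 for G2/M and 3412 against at most 796 for S. The labels were called from RNA of the same cells, so genes that vary with the scored lists follow them by construction, and this exchange decides nothing about chance. In the 3 lines there are 4 exchanges, too few for a share under 0.05 (1421 and 1122 genes with the real labels, at most 0 with others by edgeR).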
